A study of Mus musculus with 28 samples.

How the data were processed

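The series measured RNA in microglia, the resident immune cells of the brain, sorted from mouse primary somatosensory (S1) cortex that had been dissected into layers 1-4, layer 5 and layer 6, and in nuclei of undivided S1 cortex. There were 28 libraries in 14 groups of 2. Of these, 24 were single-cell libraries in 3 sets: microglia of Cx3cr1-GFP reporter mice at postnatal day 14 (P14), the same line at day 60 (P60), and P14 microglia from a Fezf2 cohort with control and knockout (KO) mice. The other 4 were libraries of nuclei from wild-type and Fezf2 KO cortex at day 14. The labels call the single-cell controls Fezf2 heterozygous, while the deposited tables call them wild type, so they are called control here.

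The deposited tables held raw UMI counts (counts of distinct RNA molecules) per gene and cell, which the authors made from 10x Genomics libraries per the labels' protocols. The submitters' processing notes name Cell Ranger, Seurat 3.1.1 and the mm10 genome, and which cells were kept is not given in the sources used here. No doublet caller was run. Each cell's state or type was taken from the authors' deposited annotation. The state names were chosen by the authors on these samples, so a state named after a layer is not independent evidence of a layer difference.

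The 24 single-cell libraries held 39035 cells, from 180 to 5209 per library, with 1578572 to 31278350 UMIs per library and a median of 5647 to 9660 UMIs per cell. The 4 nuclei libraries held 12690 nuclei and 38354467 to 51756706 UMIs each. Every deposited single cell was annotated as a microglial state, so summing all cells in place of microglia was the same calculation. Within a group of the Fezf2 cohort, the replicate code in the deposited annotation numbered the libraries. The nuclei libraries were numbered 1 for the female and 2 for the male library of each genotype, as the deposited table names them. The nuclei annotation gave excitatory neurons without their layers, so classes by layer were not analysed here.

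Counts were summed per library, and per library and cell class for nuclei with at least 50 nuclei in each library, because cells are not replicates. The sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr by group), with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are log2 with their standard error (SE), and levels are CPM, counts scaled to the library size, with the standard deviation (SD) over libraries. The layer comparison over 3 sets used 18 libraries with the set as a term. Comparisons of KO with control and of P60 with P14 averaged the per-layer differences. Alternatives were DESeq2 1.42.0, RLE scaling, no low-count filter, sums of homeostatic states only, each library left out in turn, and the replicate number within its set and genotype as a term (the replicate block). Where leaving out a library left a group with 1, that library was taken to vary like the other groups. These choices and the gene lists were made before the data were examined.

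Replicate numbers were checked for pairing before calls were compared. Deviations from the group mean in libraries with the same number, for different layers of the same set and genotype, correlated across genes at 0.3 to 0.6, above 0.1 for each pair. The numbers therefore pair layers within a preparation. Between KO and control with the same code in the annotation the correlation was 0.14 to 0.25, so the code as 1 term for both genotypes was added as an alternative. These correlations rest on 2 preparations per genotype, and the column names number the first preparation differently in KO and control. Layers of a preparation are thus not independent samples, and a mean over layers rests on 2 preparations per genotype or age. The block takes out the spread between preparations, so it bears on layer differences and does not test genotype or age. The edgeR p-values of the main fit measure the spread between libraries and count layers of a preparation as independent. Those with the block measure the spread left after differences between preparations are taken out. Nothing in the labels says how many mice each preparation pooled, so either spread may be partly technical.

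Gene lists numbered 39, and those with at least 3 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with an estimated correlation, and with fry. Shares of states were compared with exact two-sided permutation tests within sets or layers. Shares were computed with numpy 2.4.6 and scipy 1.17.1. Genes were named by a fixed rule. It took the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap, with at least 10 CPM in the higher group and without predicted genes. It added up to 4 called members of each list, or 2 members with the highest CPM as values where none was called, and a fixed set of microglial and myelin genes. Coordinates are mm10 from GENCODE vM21.

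The tests were tried on simulated data in which 200 genes were changed by 2-fold or 4-fold. For layer 6 against layers 1-4 at P14 (12521 genes) 38% of 2-fold and 77% of 4-fold changes were recovered. For the 3 sets together (12441 genes) these shares were 83% and 95%, and for KO against control over the layers (12112 genes) 87% and 96%, with 48% and 82% in layer 5 alone. For P60 against P14 (12257 genes) they were 83% and 94%, and for excitatory nuclei (17178 genes) 79% and 94%. False calls made up 4.8% to 8.7% of the calls in these simulations, which contained no shared preparation effect.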

Results

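RNA was counted in microglia of the S1 cortex by layer, in 3 single-cell sets of 6, 6 and 12 libraries, and in 4 libraries of cortical nuclei. The design asks whether microglia differ between layers 1-4, layer 5 and layer 6, whether this changes with age, and what changes without Fezf2, a transcription factor that specifies subcerebral projection neurons of layer 5. Single-cell libraries held 1578572 to 31278350 UMIs and the nuclei libraries 38354467 to 51756706. Each group had 2 libraries.

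Fezf2 lies on chromosome 14 from 12342094 to 12348189 on the minus strand (mm10, protein coding). In excitatory neuron nuclei it stood at 0.485 ± 0.16 CPM (SD, n = 2) in the KO and 8.77 ± 0.94 CPM in the wild type, a log2 fold change of -4.13 ± 0.24 (SE, edgeR adjusted p = 0.00034). In the sorted microglia of the Fezf2 cohort it had 0 UMIs in each group, so it does not check the labels of those libraries.

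Layer 6 microglia of the 3 sets without a knockout held lower levels of Apoe and of genes of disease-associated, interferon-responsive and inflammatory microglia than those of layers 1-4. Apoe, a lipid carrier (chromosome 7, 19696109 to 19699188, minus strand), stood at 550 ± 360 CPM in layer 6 and 1310 ± 400 CPM in layers 1-4 (SD, n = 6 each), with a log2 fold change of -1.58 ± 0.27. Cst7, a cysteine protease inhibitor, fell by 1.62 on the log2 scale, Lyz2, lysozyme, by 1.19, and Cd34, a sialomucin, by 1.15. The edgeR adjusted p was 0.0034 for Apoe, 0.001 for Cst7 and Lyz2, and 6.1e-05 for Cd34. Higher in layer 6 were Pde1b, a phosphodiesterase (log2 0.84 ± 0.11), and the purinergic receptor gene P2ry13 (0.39 ± 0.08). P2ry12 and Tmem119, markers of homeostatic microglia, had log2 fold changes of -0.07 ± 0.09 and -0.06 ± 0.07 and did not pass the test. Transcripts known from other cells moved as well. Pf4, abundant in border macrophages, fell by 2.91 on the log2 scale (SE 0.60), while the neuronal gene Snap25 rose by 0.88 ± 0.27. The lists of pan-neuronal and myelin genes were not called by camera, with adjusted p of 0.97 and 0.98. AY036118 and Lars2, viewed per library for technical differences, were higher in layer 6 than in layers 1-4 of each preparation. AY036118 stood at 24.5 and 259 CPM in layers 1-4 and 6 of P14 replicate 2, and at 141 and 194 in P60 replicate 1. Gm42418 was higher except in P60 replicate 1 (1900 and 1830), and Rps12 went both ways. A technical difference between layers was not tested.

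The layer 6 difference ran through several groups of genes fixed beforehand. Of 73 nuclear genes of oxidative phosphorylation, 59 fell and 0 rose, with 67 lower when adjusted over the list alone. Of 28 lysosome genes 20 fell, among them Ctsd (log2 -0.46 ± 0.07) and Ctsb (-0.54 ± 0.09), and 1 rose; adjusted over the list alone 21 fell. Of 23 interferon response genes 15 fell, 19 adjusted over the list alone, including Isg15 (-1.18 ± 0.22) and Irf7 (-1.42 ± 0.30). Of 20 axon tract and disease-associated genes 12 fell, 15 adjusted over the list alone, and of 17 inflammatory cytokine genes 7 fell, 9 adjusted over the list alone, including Ccl3 (-1.51 ± 0.33). The lipid and cholesterol list went both ways, with 5 of 23 genes higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.72). Camera called 14 of the 32 lists lower. For the 5 lists above the adjusted p was 0.22 with an estimated correlation, so these calls were lost.

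In all, edgeR called 1681 of 12441 genes between layer 6 and layers 1-4, 469 higher and 1212 lower, and the replicate block called 5603. The count was 313 without the P14 set, 2 without the P60 set and 5 without the Fezf2 controls, and 98 without P60 replicate 2. Without P60 replicate 1 it was 663 and without P14 replicate 1 it was 2599. Leaving out 1 library of layers 1-4 gave 3054 (P14 replicate 1), 411 (P14 replicate 2), 325 (P60 replicate 2), 796 (control replicate 1) and 2753 (control replicate 2). Leaving out 1 library of layer 6 gave 584 (P14 replicate 1), 354 (P60 replicate 1), 929 (P60 replicate 2) and 989 (control replicate 2). The sets and preparations were left out as alternatives chosen after seeing the data. Layer 5 against layers 1-4 gave 0 genes with edgeR (2582 at an unadjusted p under 0.05), 151 with DESeq2 and 3898 with the replicate block. The layer 5 count was 238 without replicate 1 of P14 layers 1-4, 2 without replicate 1 of P14 layer 6, 1 without replicate 1 of P60 layers 1-4, 5 without P14 replicate 1 and 1 without control replicate 1.

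**Figure D1:**
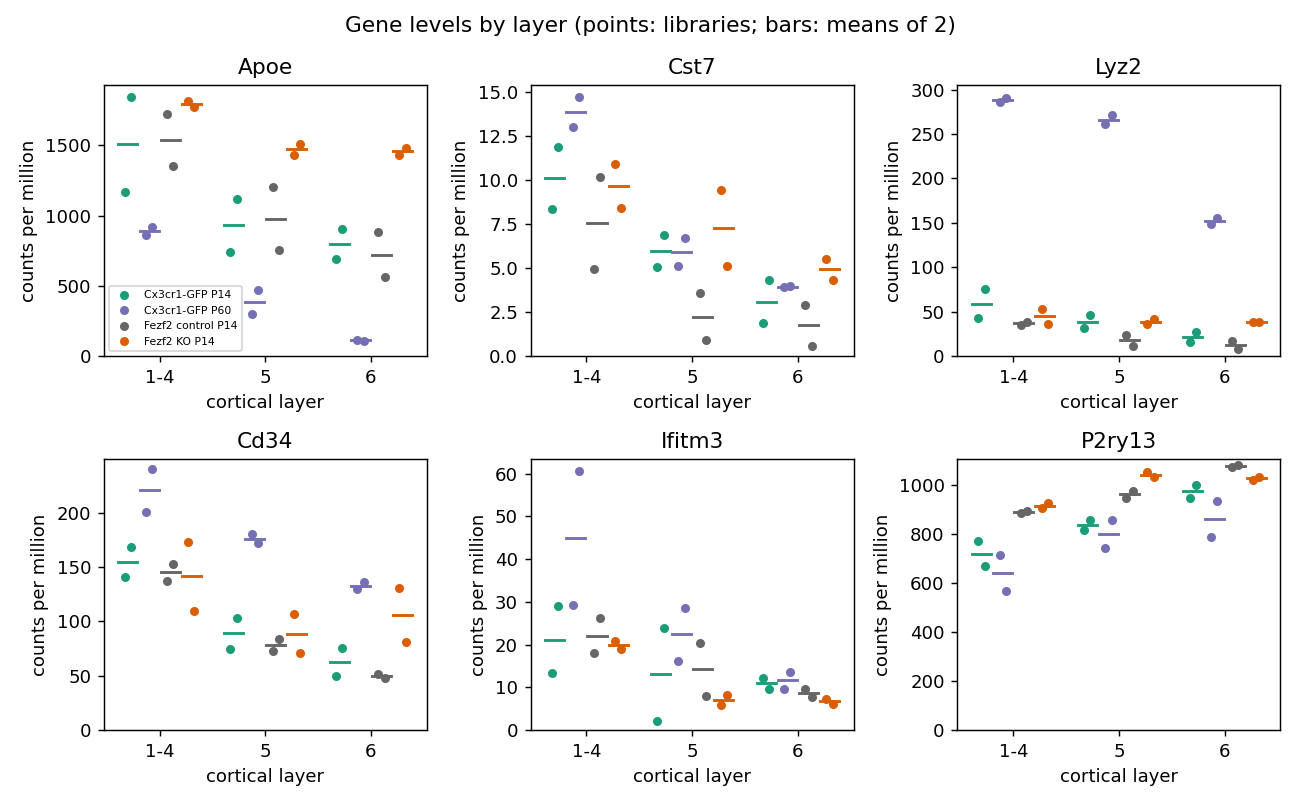
CPM of 6 genes (vertical axes, from 0) against cortical layer, for the 4 kinds of microglia; points are libraries and bars the means of 2. Apoe averaged 550 CPM in layer 6 and 1310 CPM in layers 1-4 over the 3 sets without a knockout.

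Within single sets few genes passed in the main fit, which leaves out the pairing of layers within a preparation. More passed with the replicate block, which takes that pairing into account. At P60, edgeR called 11 genes between layer 6 and layers 1-4, 10 of them lower. Apoe fell by 2.96 on the log2 scale (SE 0.20, adjusted p = 0.00061), the chemokine gene Ccl2 by 2.40 (SE 0.21, adjusted p = 0.0027) and Ccl3 by 1.37 (SE 0.17, adjusted p = 0.023). The count was 4282 without replicate 1 and 17 without replicate 2 of layers 1-4, 2 without replicate 1 and 1 without replicate 2 of layer 6, 205 with DESeq2 and 2457 with the replicate block. Layer 5 against layers 1-4 at P60 called 2 genes, Ccl2 and Ccl3, with 364 under the block, 4 with DESeq2 and 3175 without replicate 1 of layers 1-4. Without replicate 1 of layer 5 it called 1, and without replicate 2 it called 0. Between layer 6 and layer 5 at P60 only Apoe was called by edgeR (log2 -1.77 ± 0.20, adjusted p = 0.05 after rounding), with 13 genes under the block, 2 with DESeq2 and 0 with RLE scaling. It called 0 without replicate 2 of layer 5 or without either layer 6 library, and 2 without either library of layers 1-4.

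At P14 edgeR called 0 genes in layer 5 against layers 1-4 (331 at an unadjusted p under 0.05, 1 with DESeq2, 1721 with the block, 2 without replicate 1 of layers 1-4). In layer 6 against layers 1-4 it called 0 (734 unadjusted, 9 with DESeq2, 2924 with the block, 2 without replicate 1 of layers 1-4). In layer 6 against layer 5 it called 0 (53 unadjusted, 0 with DESeq2, 18 with the block). Apoe had a log2 fold change of -0.88 ± 0.28 in layer 6 against layers 1-4 (edgeR adjusted p = 0.58, and 2e-06 with the block). In the Fezf2 controls edgeR called 0 genes in layer 5 (290 unadjusted, 3 with DESeq2, 284 with the block) and 0 in layer 6 (702 unadjusted, 17 with DESeq2, 1635 with the block), with Apoe at -1.07 ± 0.23 in layer 6 (edgeR adjusted p = 0.46, and 7.7e-12 with the block).

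Cells in the authors' Apoe+ state made up 4.36% of layer 6, 7.36% of layer 5 and 13.8% of layers 1-4 microglia (means of 6 libraries each), with an exact permutation adjusted p of 0.014 for each deep layer. The Innate immune state held 2.58% of layer 6 and 4.98% of layers 1-4, and the Inflammatory state 1.22% and 3.51%, each with an exact permutation adjusted p of 0.014. In layer 5 the Inflammatory share was 2.24% (exact adjusted p = 0.022, and 0.075 with the replicate block), and the Innate immune share was 3.53% (exact adjusted p = 0.17). The smallest p that these 216 arrangements can give is 0.0093. At P14 the state named after layers 5-6 held 3.65% ± 3.7 of layers 1-4 and 81.9% ± 2.8 of layer 6 (SD, n = 2), and at P60 the Homeostatic2 state rose from 25.0% ± 14 to 88.3% ± 6.3 as values without a test.

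**Figure D2:**
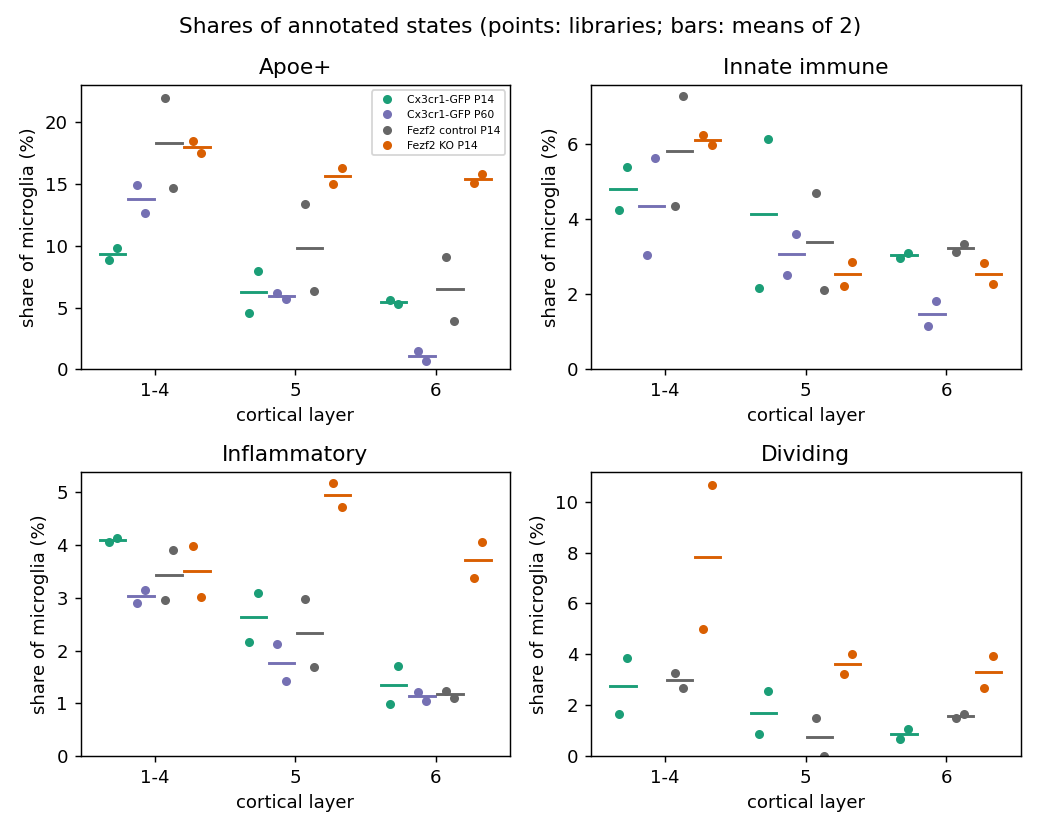
Shares of microglia in 4 annotated states (vertical axes in percent, from 0) against cortical layer; points are libraries and bars the means of 2. No Dividing state was annotated at P60. The Apoe+ share averaged 13.8% in layers 1-4 and 4.36% in layer 6 over the 3 sets without a knockout.

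Microglia of Fezf2 KO cortex, averaged over the layers, held more RNA of cell division genes than controls. Mki67, a proliferation marker, stood at 54.1 ± 41 CPM in the KO and 8.0 ± 10 CPM in controls (SD, n = 6 libraries from 2 preparations each), with a log2 fold change of 2.93 ± 0.42. Top2a, a topoisomerase, rose by 2.77 ± 0.32 and Cenpf, a kinetochore protein, by 2.55 ± 0.18, with edgeR adjusted p of 0.0028 and 0.00023. These p-values count the layers of a preparation as independent. With the layers summed per preparation, 0 of the 34 called named genes stayed called. Of 26 cell division genes 16 rose, 23 adjusted over the list alone, and 0 fell (camera adjusted p = 2.2e-23, adjusted p = 0.24 with an estimated correlation). Of 22 immediate early genes 4 fell, 11 adjusted over the list alone, among them Ier2 (-0.96 ± 0.14), and of 22 interferon genes 3 fell, 10 adjusted over the list alone, among them Oasl2 (-1.35 ± 0.26). For the immediate early list the adjusted p was 0.24 with an estimated correlation, and for the interferon list the adjusted p was 0.28 with an estimated correlation. Ddit4, a stress-response gene, fell by 1.34 on the log2 scale (SE 0.12), and Apoe had a log2 fold change of 0.61 ± 0.13 (edgeR adjusted p = 0.056, and 2.9e-13 with the block, which does not test genotype).

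Averaged over the layers edgeR called 171 of 12112 genes, 113 higher and 58 lower, while at an unadjusted p under 0.05 there were 706 higher and 834 lower. When the 3 layers of a preparation were summed, so that 2 preparations were set against 2, edgeR called 0 genes (519 at an unadjusted p under 0.05). That alternative was chosen after seeing the data. The count was 4 without control replicate 1, 42 without control replicate 2, 363 without KO replicate 2 (174 higher and 189 lower), 287 with DESeq2 (162 and 125), 2305 with the replicate block and 1162 with 1 replicate code for both genotypes (the shared code). The replicate block lies within genotype and takes out the spread between preparations that a genotype difference has to exceed, so it does not test genotype. The shared code still counts the layers of a preparation as independent, so it does not test genotype at the level of preparations. Leaving out a single library of control replicate 1 gave 109 (layers 1-4), 84 (layer 5) and 59 (layer 6), and of KO replicate 1 gave 90 (layer 5) and 89 (layer 6). In cells of the homeostatic states alone 29 genes were called, 7 higher and 22 lower, and Cenpf had a log2 fold change of -0.46. Of the 113 genes higher in the KO, 50 were tested in those cells, and their median log2 fold change was 0.32 there and 0.96 over all cells, in states that were assigned from expression. KO replicate 1 held 2310 to 2520 CPM of Rps12, against 26 to 62 CPM in the other libraries of the cohort, so ribosomal genes are not compared between genotypes. Control replicate 1 also stood apart, with 0 CPM of Trim30d against 26 to 40.5 in the other libraries of the cohort, 7.37 to 9.02 CPM of Trim12a against 59.5 to 88.3, and 13.1 to 17.9 CPM of Gt(ROSA)26Sor against 0 to 1.87. These genes were singled out after their values were seen. Replicate 1 of both genotypes had 0 CPM of the Y-linked gene Ddx3y and replicate 2 of both had 27.4 to 40.6 CPM.

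By layer, edgeR called 0 genes between KO and control in layers 1-4 (527 unadjusted, 4 with DESeq2, 86 with the shared code, 50 without KO replicate 2, 1 without replicate 1 of KO layers 1-4 and 1 without control replicate 2) and 0 in layer 5 (429 unadjusted, 28 with DESeq2, 33 with the shared code, 34 without KO replicate 2, 1 without either library of KO layers 1-4 and 1 without control replicate 2). In layer 6 it called 4, including Cenpf (log2 2.96 ± 0.34, adjusted p = 0.032) and Tpm3-rs7 (-1.53 ± 0.21, adjusted p = 0.043), with 170 under the shared code and 50 with DESeq2. That count was 57 without KO replicate 2, 0 without any 1 of the 4 layer 6 libraries, 8 without either library of KO layers 1-4, 2 without either of control layer 5, and 1 without either of KO layer 5 or of control layers 1-4. Without control replicate 1 or KO replicate 1 it was 0 and without control replicate 2 it was 1. The test of a layer difference in the KO effect called 0 genes for layer 5 against layers 1-4 (55 unadjusted, 0 with DESeq2) and 0 for layer 6 (112 unadjusted, 0 with DESeq2, 46 with the block, 0 with the shared code).

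The Dividing state held 4.92% of KO and 1.77% of control microglia (means of 6 libraries), higher in the KO in each layer, with an exact permutation p of 0.0093 and an adjusted p of 0.074. The Inflammatory state held 4.05% and 2.31% (exact adjusted p = 0.074), and the Apoe+ state 16.4% and 11.6% (exact adjusted p = 0.17), so no state passed. The Apoe+ share in KO and control was 18% ± 0.69 and 18.3% ± 5.2 in layers 1-4, 15.7% ± 0.89 and 9.86% ± 5.0 in layer 5, and 15.4% ± 0.56 and 6.51% ± 3.7 in layer 6 (SD, n = 2). With the layers averaged per preparation the smallest exact p is 0.33.

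Microglia at P60 held more RNA of some cytokine genes and of MHC class I genes than at P14, and less of cell division and ribosomal genes. Srgn, the proteoglycan serglycin, stood at 250 ± 52 CPM at P60 and 22.4 ± 9.1 CPM at P14 (SD, n = 6 libraries from 2 preparations each), with a log2 fold change of 3.53 ± 0.12 (edgeR adjusted p = 4.9e-08). The chemokine genes Ccl4 and Ccl3 rose by 3.91 ± 0.43 and 2.70 ± 0.15, while Cenpf fell by 3.71 on the log2 scale. Of 82 ribosomal protein genes 78 fell, 78 also when adjusted over the list alone. Of 23 cell division genes 19 fell, 21 adjusted over the list alone, and of 11 MHC class I genes 10 rose, 10 adjusted over the list alone. Of 17 inflammatory cytokine genes 6 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.0048). For the ribosomal and cytokine lists the adjusted p was 0.40 with an estimated correlation, and for each of the other 2 the adjusted p was 0.42 with an estimated correlation. In all edgeR called 4919 of 12257 genes, 2472 higher and 2447 lower, with 1686 when the layers of a preparation were summed and 1818 without P60 replicate 2. The ages come from separate tables, so age and batch cannot be told apart.

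Excitatory neuron nuclei of the Fezf2 KO held lower levels of several genes of deep-layer neurons. Tshz2, a marker of near-projecting neurons, stood at 1.38 ± 0.47 CPM in the KO and 102 ± 31 CPM in the wild type (SD, n = 2), and Foxp2, a transcription factor of corticothalamic neurons, at 20.8 ± 2.0 and 161 ± 30 CPM, each with an edgeR adjusted p of 0.00019. Of 16 corticothalamic genes 6 fell and 1 rose, 9 and 1 adjusted over the list alone, among them Syt6 (log2 -2.50 ± 0.27) and Tle4 (-1.42 ± 0.16). Of 24 subcerebral genes 4 fell, 7 adjusted over the list alone, including Tox (-1.50 ± 0.15). Of 9 near-projecting and subplate genes 3 fell and 1 rose, 5 and 1 adjusted over the list alone. For these 3 lists the adjusted p was 0.99 with an estimated correlation. Nr4a2, a nuclear receptor, rose by 2.11 ± 0.12, Galnt14, a glycosyltransferase, by 2.19 ± 0.28 and Adarb2 by 1.75 ± 0.12. Adarb2 was also in a set of inhibitory neuron markers written down beforehand. Whether RNA from inhibitory neurons entered these sums was not tested. In all edgeR called 274 of 17178 genes, 129 higher and 145 lower, with 517 under DESeq2. The count was 124 without KO replicate 1, 1739 without wild-type replicate 1 and 1010 without wild-type replicate 2.

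**Figure D3:**
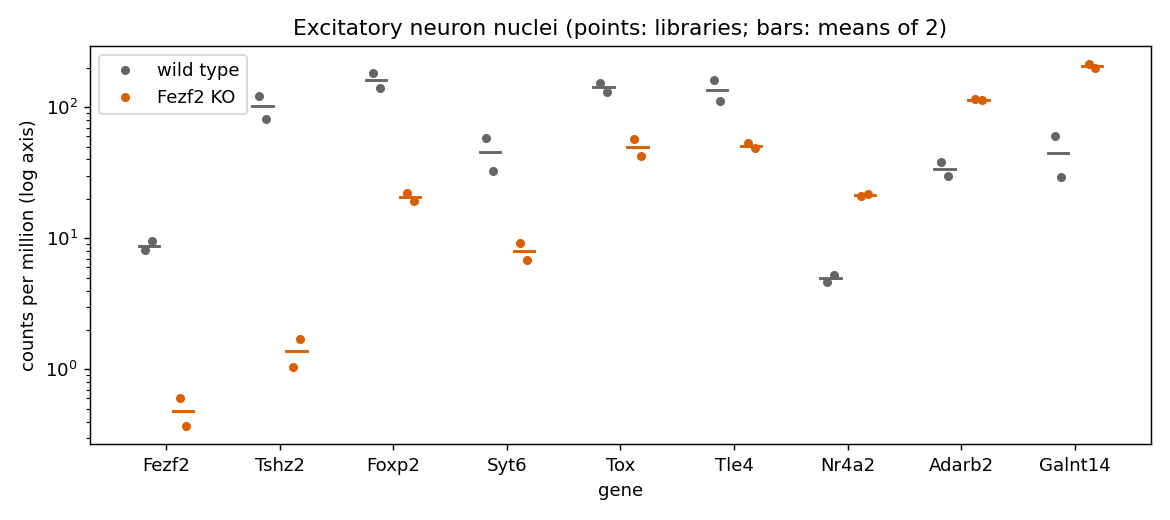
CPM (log axis) of 9 genes in excitatory neuron nuclei of wild-type and Fezf2 KO cortex; points are libraries and bars the means of 2. Foxp2 fell from 161 to 20.8 CPM and Nr4a2 rose from 4.95 to 21.4 CPM.

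In the other classes of nuclei edgeR called fewer genes. Libraries held 301 to 370 inhibitory neurons against 1861 to 2375 excitatory neurons, and recovery was not simulated for the other classes. These counts therefore do not compare how much the classes changed. Fhit and Gm48321, both within 20 Mb of Fezf2, were among the genes called in inhibitory neurons. In all, inhibitory neurons had 9 called genes, 8 higher, led by Crhbp, a corticotropin-releasing hormone binding protein (log2 1.67 ± 0.21, edgeR adjusted p = 0.0021). That count was 34 without KO replicate 1, 220 without KO replicate 2, 113 without wild-type replicate 1 and 23 without wild-type replicate 2. Astrocytes had 4, including Fam19a2 (log2 -2.50 ± 0.20) and Hs3st4 (-1.96 ± 0.32), and 2 with DESeq2. Hs3st4 was also in a set of corticothalamic neuron markers written down beforehand. Astrocytes held 134 to 197 nuclei per library, and whether RNA from neurons entered their sums was not tested. Without KO replicates 1 and 2 and wild-type replicates 1 and 2 in turn the astrocyte count was 33, 22, 80 and 38. Oligodendrocytes had 0 with edgeR (306 unadjusted, 0 with DESeq2, 2 without wild-type replicate 2), and microglia with macrophages had 0 (252 unadjusted, 0 with DESeq2, 244 without wild-type replicate 1). Excitatory neurons made up 63.1% ± 1.6 of KO and 67.5% ± 1.3 of wild-type nuclei, and microglia with macrophages 10.9% ± 0.79 and 7.85% ± 1.0 (SD, n = 2), where the smallest exact p is 0.33.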

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

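The tests of differences between ages were chosen after the results were seen, while the layer difference of the Fezf2 KO effect was planned. Camera with the preset correlation called gene lists whose KO effect differed between layers, at a threshold of 0.05. In layer 5 against layers 1-4 the KO effect was higher by a median log2 of 0.21 over axon tract and disease-associated genes and 0.29 over cell division genes, where the adjusted p was 0.75 with an estimated correlation for both. In layer 6 against layers 1-4 the median differences were 0.23 for lysosome genes, 0.24 for immediate early genes, 0.26 for axon tract and disease-associated genes and 0.36 for cell division genes. They were 0.22 for mitochondrially encoded genes and 0.12 for oxidative phosphorylation genes. The adjusted p was 0.04 with an estimated correlation for the lysosome list, 0.50 for the immediate early list and 0.80 for the others.

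The layer difference also differed between P60 and P14 for some genes once the replicate block was used. With the block 5 genes differed in layer 5 and 33 in layer 6, against 0 and 0 with edgeR without it, where 89 and 207 genes had an unadjusted p under 0.05. Apoe fell in layer 6 by 0.88 on the log2 scale at P14 and by 2.96 at P60. The difference was -2.08 ± 0.38 in the fit without the block, which did not call Apoe. With the block its edgeR adjusted p was 7.7e-05. The ages come from separate tables, so age and batch cannot be told apart here either.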

How the results depend on the processing

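Counts of genes are given for each setting that moved them by more than 1.5 times, and the cause was not tested. The sets left out, the shared replicate code, the layers summed or averaged per preparation, the preparations left out and the block for shares and lists were chosen after seeing the data. Of the called named genes, 320 of 322 stayed called with RLE scaling, 316 of 322 without a low-count filter, 304 of 313 with DESeq2 and 322 of 322 with the replicate block, which does not test genotype or age. In homeostatic states 218 of 262 stayed called and 5 reversed, and with 1 set left out 55 of 280 stayed. With the layers summed per preparation 93 of 170 calls for KO and age stayed, 93 of 136 for age and 0 of 34 for the KO, and with 1 library or preparation left out 4410 of 5274 stayed, counted over genes and removals. Of the called lists, 2 of 171 held with an estimated correlation, 45 of 171 with fry and 164 of 171 with the block. The smallest library, control replicate 2 of layer 6, held 180 cells.

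Without a low-count filter the counts in layer 5, layer 6 and layer 6 against layer 5 were 93, 245 and 14 at P14 and 82, 709 and 21 at P60. In controls they were 37 and 58 in layers 5 and 6, and for KO against control 93, 89 and 158 in layers 1-4, 5 and 6, 500 (242 higher and 258 lower) over the layers and 3 for the layer 6 difference of the KO effect. In nuclei they were 495 in excitatory neurons, 122 in inhibitory neurons, 44 in astrocytes, 1 in oligodendrocytes and 12 in microglia with macrophages. DESeq2 gave 1 and 9 in layers 5 and 6 at P14, 4, 205 and 2 at P60, 151 in layer 5 of the 3 sets, 3 and 17 in controls, 4, 28, 50 and 287 for the KO, 517 in excitatory neurons and 2 in astrocytes. RLE scaling gave 0 in layer 6 against layer 5 at P60.

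The replicate block gave 1721, 2924 and 18 at P14, 364, 2457 and 13 at P60, 3898 and 5603 over the 3 sets and 284 and 1635 in controls. For the KO, where it does not test genotype, it gave 1105, 390, 1035 and 2305. For the layer 6 difference of the KO effect, which compares layers within preparations, it gave 46, against 0 with the shared code. In nuclei, where the number stands for sex, it gave 910, 238 and 20 in excitatory neurons, inhibitory neurons and astrocytes. The Inflammatory share in layer 5 kept its difference of -1.27 points with an exact adjusted p of 0.075, and the block ended no other call of a named gene or share. With 1 replicate code for both genotypes the KO counts were 86, 33, 170 and 1162. Homeostatic states alone gave 1, 4 and 0 at P60, 1 in layer 5 of the 3 sets, and 1 in layer 6 and 29 (7 higher and 22 lower) over the layers for the KO. The reversed genes there were Tk1 (0.02) and Ube2c (0.25) in layer 6 of the 3 sets, Cenpf (-0.66 in layer 6 and -0.46 over the layers) and Diaph3 (-0.28) for the KO. Layer 6 of the 3 sets gave 313, 2 and 5 without the P14, P60 and control sets. Layers summed per preparation gave 0 for the KO and 1686 for age.

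With 1 library or preparation left out, counts ranged from 0 to 2 in layer 5 and in layer 6 and stayed at 0 for layer 6 against layer 5 at P14. At P60 they ranged from 0 to 3175, 1 to 4282 and 0 to 2. They ranged from 0 to 238 and 98 to 3054 over the 3 sets and stayed at 0 in controls. For the KO they ranged from 0 to 50, 0 to 34, 0 to 57 and 4 to 363, and stayed at 0 for both layer differences. For age the range was 1818 to 5684. In nuclei the ranges were 124 to 1739, 23 to 220, 22 to 80, 0 to 2 and 0 to 244 in excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes and microglia with macrophages.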

Other observations

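The tests of the linked locus, of the reference for KO replicate 1, of minor states, of summed preparations, of splits with the replicate block and of neuron and myelin RNA were chosen after the results were seen, and the group of genes the last of these covers was also changed afterwards. The tests of other splits without the block and of pairings of preparations were planned. Gene lists not described so far moved too. In layer 6 against layers 1-4, 37 of 82 ribosomal protein genes fell and 1 rose, 45 and 3 adjusted over the list alone (camera adjusted p = 3.2e-07, adjusted p = 0.42 with an estimated correlation). Of 6 MHC class II genes 5 fell, 6 adjusted over the list alone, and of 16 glycolysis genes 9 fell and 1 rose, 9 and 1 adjusted over the list alone (adjusted p = 0.22 with an estimated correlation for both). At P60 against P14, 16 of 23 lipid and cholesterol genes fell and 4 rose, 16 and 4 adjusted over the list alone (adjusted p = 0.40 with an estimated correlation), among them Sqle, a cholesterol synthesis enzyme, with a log2 fold change of -3.70 ± 0.26.

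The first pattern is the 171 genes that differed between Fezf2 KO and control microglia; among 100 splits of the libraries within layers 2 gave as many genes, the real split with 171 included and 2653 for the highest other, but all except 3 of these splits break up preparations, whose layers are not independent. With preparations kept whole there are 3 pairings, too few for a share under 0.05. The one by replicate code called 2653 genes and points to a structure of the samples. It parts libraries with and without Ddx3y RNA. Also parted, and singled out after their values were seen, were Gm42418 and Lars2. Gm42418 stood at 458 to 810 CPM in replicate 1 and 2790 to 4200 in replicate 2, Lars2 at 21.7 to 65.3 and 159 to 324. With that code as a term, which is balanced over genotypes, the KO count was 1162. That fit still counts the layers of a preparation as independent, so it does not test genotype at the level of preparations. With the layers summed per preparation edgeR called 0 genes (519 unadjusted), so the spread between preparations of a genotype may account for the pattern. Genes within 20 Mb of Fezf2 were called more often, with an odds ratio of 4.99 (9 of 139 genes against 162 of 11853, Fisher exact p = 0.00017). The odds ratio was 4.11 in excitatory nuclei and 27.2 in inhibitory neuron nuclei, the latter on 2 called genes near Fezf2. Variants linked to the locus may account for some of the 9 microglial genes but leave 162 open. Without KO replicate 1 the median log2 change of the 171 genes was 0.94 times that with it. Their change thus did not rest on that preparation alone. They were called with it in the fit, and a gene shifted only there spreads widely within the KO and is seldom called. The ratio was thus largely set by the choice of genes and cannot rule out another reference for that preparation. The median of 50 of the 113 genes higher in the KO was 0.33 times as large over homeostatic-state cells. That decides nothing on minor states, since states were assigned from expression and the other genes were not tested there. A genotype effect stays open, since the test of 2 summed preparations against 2 called 0 genes and may miss one.

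The second pattern is the layer difference over the 3 sets. Of 32 splits that part the libraries of each preparation, 1, the real one, gave 1681 genes for layer 6 and the highest other gave 9. That share is under 0.05, which argues against chance, but it is the smallest that 32 splits can give. The other splits hold the layer difference in their residual spread, so their low counts add nothing. For layer 5 the count of 0 decides nothing, since all 32 splits reach it. With the replicate block, which fits the pairing of layers, 1 of 32 splits, the real one, gave as many genes for each layer. It called 5603 for layer 6 (highest other 4153) and 3898 for layer 5 (highest other 1826). This again argues against chance for both layers, at the smallest share possible. The highest others exchange the layers of a single preparation and so keep most of the layer difference. Among 1194 genes lower in layer 6 the median change over homeostatic-state cells was 0.98 times that over all cells. For these genes as a set this argues against a loss of minor states as the cause. It does not speak for single genes such as Apoe, nor for shifts between the homeostatic states, which were assigned from expression. Of the 469 genes that rose in layer 6, 0.85% were in the neuron or myelin lists, which could reach 5.12% at most, so that share could not decide; 16.7% of the 24 tested list genes rose, against 3.77% of all genes, but 3 of the 24 fell, so RNA from neurons and myelin may contribute.

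The third pattern is the 4919 genes that differed between P60 and P14. Of 100 splits of the libraries within layers 1, the real one, gave as many genes, and the highest other gave 2314, but all except 3 of these splits break up preparations, whose layers are not independent. With preparations kept whole there are 3 pairings, too few for a share under 0.05, with 4919 genes for the real one and 0 for the highest other, which decides nothing on preparations, since those pairings hold the age difference in their residual spread. With the layers summed per preparation edgeR called 1686 genes, which argues against the spread between preparations within an age as the whole cause. The ages come from separate tables, so age and batch cannot be told apart.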
